A study of Mus musculus with 16 samples.

How the data were processed

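Labelled cDNA from total RNA of whole mouse brain was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. Per the labels' protocols, RNA was isolated with Trizol and labelled with biotin using the GeneChip WT Terminal Labeling Kit. The submitters' processing notes name GCOS, GCRMA, Partek and RMA without a version or the step each was used for. The deposited values are log2 probe set summaries with 2 decimals, which the authors had normalised between arrays, as their medians of 6.01 to 6.05 show. No detection p-values, scan dates or probe-level intensities were used here.

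The deposited table holds 28944 probe sets for 16 arrays and no other samples. Gene symbols came from GEO's platform annotation: 21789 probe sets had 1 symbol, 1621 had several and 5534 had none. Only probe sets with 1 symbol entered the gene-level tests. For the 999 genes with more than 1 such probe set, the one with the highest mean over all arrays was used, which gave 19938 genes. No filter on dim probe sets was applied. The order of genes along chromosomes came from the RefSeq annotation of GRCm38.p6, in which 19916 of the tested genes were found.

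Groups were taken from the labels: C57BL/6 or TNF knockout, naive or 24 h after permanent middle cerebral artery occlusion, 4 arrays each. No 2 arrays held identical values. A linear model with 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 7.52 prior degrees of freedom). The contrasts tested were stroke against naive in each genotype, the genotypes against each other in naive mice and after stroke, and the difference of the stroke changes. P-values were adjusted by the method of Benjamini and Hochberg over the 19938 genes of a contrast, with a threshold of 0.05. All tests were two-sided.

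The lists, 19 of genes and 18 of cell type markers, were fixed with the tests, the comparisons and the other settings listed below before the data were examined. Of 671 list memberships 605 matched a tested gene. Each list was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 37 lists of a contrast, and again with the correlation estimated from the residuals. Of the 56 list calls in the 5 contrasts, 24 held with an estimated correlation: 8 of 15 for stroke in C57BL/6 mice, 16 of 23 for stroke in the arrays labelled TNF knockout, and 0 of 3, 0 of 8 and 0 of 7 in the other contrasts. Members past the threshold were counted over all genes and adjusted over the list alone. The direction of the medians of lists that passed camera did not change with quantile normalization or median centring.

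The text names Tnf, then genes chosen by a rule fixed in advance. Per contrast these are from the 10 largest increases and the 10 largest decreases past the threshold with groups that do not overlap, leaving out unnamed gene models. If fewer than 5 genes pass, the 5 smallest p-values are given instead. From each list up to 4 members with the smallest p are eligible. Genes named for their position on a chromosome fall outside the rule and were chosen after their values were seen.

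Other settings were quantile normalization, median centring, leaving out the 33.3 percent of genes with the lowest mean, the mean of a gene's probe sets, testing every probe set, trended and robust variances, array weights, a threshold of 0.01, a threshold of 1.5-fold, only the groups compared, the replicate number as a block, the sample name prefix as a block, and leaving out each array in turn. An exact permutation test of the mean of a list's members per array, camera with the prefix as a term, list medians within a prefix, and a linear model of the interferon list's mean with the prefix as a term were added after seeing the data.

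The scripts were tested on simulated data with 200 genes among 19938 changed for stroke against naive in C57BL/6 mice only. They recovered 68.7 percent of genes changed by 0.5 on the log2 scale, 98.5 percent of those changed by 1 and 100 percent of those changed by 2. Of the calls 4.81 percent were false, and 0 genes were called between genotypes in naive mice, where none was changed. The simulated genes varied independently of each other, with no prefix effect and no deviant array. These rates therefore need not hold for the real arrays. Recovery was not simulated for the difference of the stroke changes, whose median SE in the real arrays was 0.141 against 0.0994 in the other contrasts. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.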

Results

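Gene expression was measured in whole brain of 8-week-old male mice with Affymetrix Mouse Gene 1.0 ST arrays, 16 in all. The arrays fall into 4 groups of 4: C57BL/6 mice and TNF knockout mice, each either naive or 24 h after permanent occlusion of the middle cerebral artery, a model of ischaemic stroke. The naive mice had no sham operation, so stroke against naive holds the surgery and the occlusion together. The labels number the arrays of a group as replicates and do not state that each came from a separate animal. If they did not, the p-values would measure only the spread between these samples. The values are log2 summaries from 1.42 to 14.53, with array medians of 6.01 to 6.05 (precision is limited by the number of arrays). Correlations between arrays of 1 group were 0.991 to 0.996. Means are given ± SD with n = 4 per group, and changes are log2 differences with the SE from limma.

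Tnf, the targeted gene, was measured first, as a check of the labels. In naive C57BL/6 mice the 4 arrays read 5.01, 5.72, 5.08 and 5.41, and after stroke they read 5.64, 5.28, 5.67 and 5.68. The naive arrays labelled TNF knockout read 6.14, 6.46, 6.47 and 6.58, and the stroke arrays with that label read 6.75, 6.60, 6.99 and 6.88. Tnf was therefore higher, not lower, in every array labelled TNF knockout, by 1.11 ± 0.14 (SE) in naive mice (limma, adjusted p = 0.00056) and by 1.24 ± 0.14 after stroke (adjusted p = 0.00010). This goes against the label, and the groups are named here as arrays labelled TNF knockout. Which part of the gene the probe set covers, relative to the deletion, is not given in the sources used here, and a probe set outside the deleted part would check nothing. After stroke Tnf differed from naive by 0.26 ± 0.14 in C57BL/6 mice (adjusted p = 0.35) and by 0.39 ± 0.14 in the arrays labelled TNF knockout (adjusted p = 0.36), neither past the threshold. All C57BL/6 readings lay below the array medians of 6.01 to 6.05. Without detection p-values it is not known whether they lay above background, so a stroke response there may have been missed.

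The comparison of stroke with naive in C57BL/6 mice asks which transcripts respond to the occlusion in mice labelled as wild type. Among the largest increases were 3 chemokine genes, whose products draw monocytes and T cells into tissue, from a list in which 6 of 26 members rose. Ccl12 went from 4.71 ± 0.33 to 8.03 ± 0.53 (3.33 ± 0.19, adjusted p = 5.5e-09), Ccl3 from 4.89 ± 0.36 to 7.83 ± 0.69, and Cxcl10 from 4.91 ± 0.17 to 7.30 ± 0.69. Lcn2, an iron-scavenging protein secreted by reactive astrocytes and neutrophils, rose 8.01-fold (adjusted p = 3.6e-05), and the protease inhibitor gene Serpina3n rose by 1.89 ± 0.20. Gpr84, a fatty acid receptor of activated microglia, rose by 1.78 ± 0.17. Hmox1, which degrades haem, rose by 1.74 ± 0.23, the pattern recognition gene Ptx3 by 1.43 ± 0.26, and the lysosomal protease gene Ctsc by 1.37 ± 0.16. The decreases were smaller. Pltp, which moves phospholipids between lipoproteins, fell by 0.64 ± 0.12, and the calcium-activated kinase gene Camkk2 fell by 0.60 ± 0.09. Slc30a3, the zinc transporter of synaptic vesicles, fell by 0.58 ± 0.09. Unc13a, which primes vesicles for release, fell by 0.56 ± 0.09 (adjusted p = 0.0016), with less in its other probe sets, down to -0.24. Npas4, a transcription factor induced by neuronal activity, fell by 0.63 ± 0.14 (adjusted p = 0.026) but passed in only 11 of the 16 fits that left out 1 array. In all counts over these 16 fits, those without an array of a group not compared kept the change and altered only the pooled spread. Such fits test the result less than those without an array of the compared groups.

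Among the lists of genes fixed before the data were examined, the markers of reactive astrocytes and of activated microglia and macrophages had the highest medians in C57BL/6 mice. Of the reactive astrocyte markers 10 of 20 rose and 0 fell (12 adjusted over the list alone; median change 0.60). Examples are Osmr (1.32 ± 0.16) and the filament gene Vim (0.78 ± 0.09). Of the activated microglia and macrophage markers 9 of 21 rose (15 adjusted over the list alone; median 0.38). Among them were the lysosomal protein gene Cd68 (1.08 ± 0.08, adjusted p = 1.9e-07) and the scavenger receptor gene Msr1 (1.19 ± 0.14). Both lists passed camera with adjusted p = 5.4e-17, and adjusted p = 0.00285 with an estimated correlation.

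Of the complement genes 5 of 15 rose in C57BL/6 mice (8 adjusted over the list alone), among them the receptor genes C3ar1 (1.33 ± 0.16) and C5ar1 (1.35 ± 0.17), Itgb2 and C4b. Camera gave adjusted p = 4.07e-06 for this list, and adjusted p = 0.00700 with an estimated correlation. Of the cytokines and their receptors 4 of 24 rose (12 adjusted over the list alone), and of the matrix and wound genes 3 of 22 rose, with Anxa2 at 0.69 ± 0.11 (11 adjusted over the list alone). Heat shock genes had 1 of 12 that rose, Dnajb1 by 0.42 ± 0.08 (4 adjusted over the list alone). Oxidative stress genes and metallothioneins had 2 of 16 that rose, Hmox1 and Txnrd1 (8 adjusted over the list alone), and Txnrd1 passed in 12 of the 16 fits that left out 1 array. These 4 lists each had adjusted p = 0.0341 with an estimated correlation. Cell death genes and p53 targets shifted upwards as a list, with 0 of 16 past the threshold over all genes and 5 adjusted over the list alone (median 0.23; camera adjusted p = 4.24e-05, adjusted p = 0.0315 with an estimated correlation).

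Further lists passed camera in C57BL/6 mice but lost the call with an estimated correlation. Chemokines had 6 of 26 members that rose (8 adjusted over the list alone; adjusted p = 2.95e-05, adjusted p = 0.103 with an estimated correlation). Interferon-stimulated genes had 1 of 23, Ifit1 (0.99 ± 0.24), and 6 adjusted over the list alone (adjusted p = 1.83e-05, adjusted p = 0.130 with an estimated correlation). Glucocorticoid-responsive genes had 3 of 14, Lcn2, Sult1a1 and Fkbp5 (5 adjusted over the list alone; adjusted p = 0.0945 with an estimated correlation). Hypoxia genes had 1 of 18, Hk2 (2 adjusted over the list alone), and NF-kB targets had 0 of 18 (5 adjusted over the list alone), each with adjusted p = 0.130 with an estimated correlation. Endothelial markers had 1 of 13, Mfsd2a (0.66 ± 0.12; 2 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.223 with an estimated correlation). This list missed the threshold without naive C57BL/6 array 1 (adjusted p = 0.0574) or 2 (adjusted p = 0.0728). Synaptic transmission genes were shifted downwards, with 1 of 20 past the threshold, the calcium channel gene Cacna1a (-0.37 ± 0.09), and 3 adjusted over the list alone. Camera gave adjusted p = 0.00658 for them, adjusted p = 0.130 with an estimated correlation, and adjusted p = 0.0755 without C57BL/6 stroke array 1. Of the 16 fits that left out 1 array, Ifit1 and Cacna1a each passed in 9, Sult1a1 in 14, Fkbp5 in 6 and Hk2 in 4.

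Of the lists that did not pass camera in C57BL/6 mice, TNF ligands, receptors and adaptors had 2 of 18 members that rose, the receptor gene Tnfrsf1a (0.57 ± 0.10) and the sheddase gene Adam17 (0.34 ± 0.09). Immediate early genes had Jun (0.51 ± 0.10) and Atf3 (0.69 ± 0.14) higher and Npas4 lower, of 25. Resident microglia markers had Fcrls higher (0.90 ± 0.17) and Siglech lower (-0.47 ± 0.11), of 12. Resting astrocyte markers had the connexin gene Gjb6 higher (0.57 ± 0.11), of 14, and circadian clock genes had Nr1d1 lower (-0.34 ± 0.08), of 14. The antigen presentation list had H2-Q4 higher, of 14. The neighbours of Tnf on chromosome 17 had Clic1, C4b and H2-Q4 higher, of 44, with a median of -0.06 and a mean of 0.01. Of the 16 fits that left out 1 array, Adam17 passed in 2, Nr1d1 in 3, H2-Q4 in 10, Siglech in 11, Atf3 in 13 and Gjb6 in 14.

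In C57BL/6 mice 0 members passed the limma threshold in the lists named next. They are the markers of neutrophils and monocytes (median 0.20; Clec4d 0.74 ± 0.21, adjusted p = 0.089), lymphocytes (median -0.10), general neurons (median 0.01, mean -0.05) and cortical excitatory neurons (median -0.09). They include inhibitory neurons (median -0.07), striatal neurons (median -0.08) and the markers of thalamus, hypothalamus and cerebellum (median -0.11). Oligodendrocytes (median 0.03), their precursors (median 0.12), pericytes, smooth muscle and fibroblasts (median -0.12) and choroid plexus and ependyma (median -0.02) belong here too. So do red blood cells (median -0.10), sex-linked transcripts (median 0.16), cell cycle genes (median -0.09) and the genes of the integrated stress and unfolded protein response (median 0.02). None of these lists passed camera (adjusted p of 0.0794 or more), and 3 of 17 neutrophil and monocyte markers passed adjusted over the list alone.

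Of 19938 genes tested in C57BL/6 mice, 334 passed the limma threshold (adjusted p under 0.05), 267 higher and 67 lower after stroke. At least a 2-fold increase was found in 24 of them, and 0 fell that far. In 1647 genes (8.26 percent) the 4 stroke arrays did not overlap the 4 naive arrays, against 2.86 percent by chance, and 313 of these were past the threshold. The count depended on single arrays: it was 139, 177 and 192 without naive C57BL/6 array 1, 2 or 3, it was 639, 167, 107 and 182 without C57BL/6 stroke array 1, 2, 3 or 4, and it was 214 without naive array 2 of those labelled TNF knockout.

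**Figure D1:**
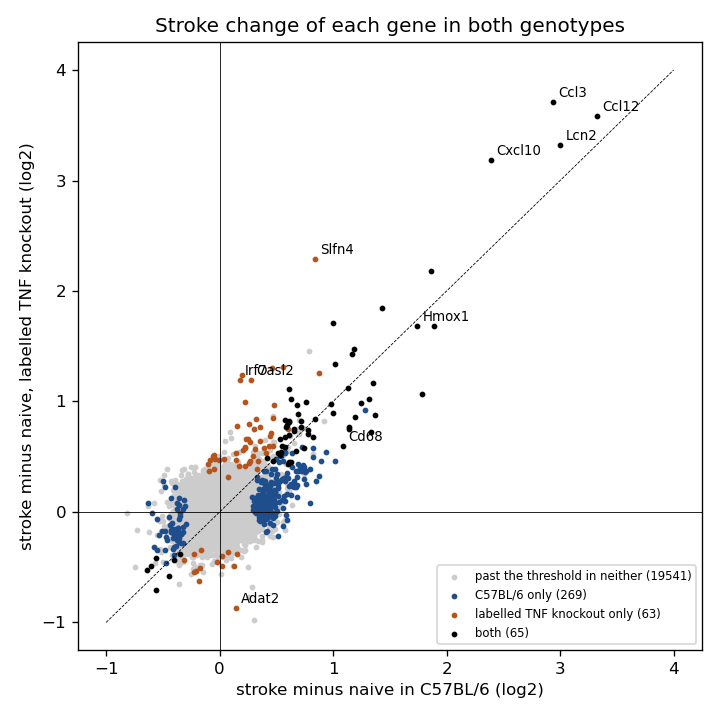
Log2 change from naive to stroke in C57BL/6 mice (horizontal axis) and in the arrays labelled TNF knockout (vertical axis), 1 point per gene, with the genes past the limma threshold coloured by the comparison they passed. Of the 65 genes past the threshold in both, 58 lie in the upper right quadrant and 7 in the lower left.

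The same comparison in the arrays labelled TNF knockout asks which transcripts respond to the occlusion in mice so labelled, in which Tnf was not lower. Ccl3 rose from 5.14 ± 0.09 to 8.85 ± 0.80 (3.71 ± 0.31, adjusted p = 2.5e-06) and Ccl12 from 4.42 ± 0.17 to 8.00 ± 0.13 (3.58 ± 0.19, adjusted p = 1.4e-09). Lcn2 rose by 3.32 ± 0.31 and Cxcl10 by 3.19 ± 0.28. Slfn4, a myeloid gene induced by interferon, rose by 2.29 ± 0.27 and the myeloid receptor gene Lilr4b by 2.18 ± 0.23. Ptx3 rose by 1.84 ± 0.26, Serpina3n by 1.69 ± 0.20 and Hmox1 by 1.68 ± 0.23. Among the decreases, Adat2, a subunit of a tRNA-editing deaminase, fell by 0.86 ± 0.13. Fabp7, a fatty acid binding protein of astrocytes and radial glia, fell by 0.63 ± 0.13, and Homer1, a scaffold of the postsynaptic density, fell by 0.55 ± 0.10. Camkk2 fell by 0.49 ± 0.09 and Pltp fell by 0.53 ± 0.12. Of the 16 fits that left out 1 array, Fabp7 passed in 10, Homer1 and Camkk2 in 12 each, and Pltp in 7.

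The sample names of these 8 arrays carry 2 prefixes, KL76 (naive arrays 1 to 3 and stroke array 1) and KL82 (naive array 4 and stroke arrays 2 to 4), whose meaning the labels do not give. With the prefix as a fixed term the changes were 3.88 for Ccl3, 3.61 for Ccl12, 3.57 for Lcn2, 3.27 for Cxcl10, -0.65 for Adat2 and -0.75 for Fabp7, all still past the threshold. Homer1 (-0.45, adjusted p = 0.13), Camkk2 (-0.42, adjusted p = 0.11) and Pltp (-0.55, adjusted p = 0.13) were not. Within KL76 and within KL82 the changes were 4.40 and 3.36 for Ccl3, 3.48 and 3.75 for Ccl12, 4.22 and 2.92 for Lcn2, and 3.87 and 2.68 for Cxcl10. They were -0.85 and -0.45 for Adat2 and -0.78 and -0.72 for Fabp7.

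Interferon-stimulated genes, which carry out antiviral defence, rose as a group in the arrays labelled TNF knockout. Of 23 members 13 rose and 0 fell (18 adjusted over the list alone), with a median of 0.52, and 0.74 within KL76 and 0.57 within KL82. Among them were Ifit1 (1.71 ± 0.24), Ifit3 (1.31 ± 0.15), Oasl2 (1.20 ± 0.12) and the transcription factor gene Irf7 (1.19 ± 0.13). Camera gave adjusted p = 3.3e-37, and adjusted p = 0.000558 with an estimated correlation. Reactive astrocyte markers rose in 11 of 20 cases (15 adjusted over the list alone; median 0.63), among them Vim (0.74 ± 0.09) and the transglutaminase gene Tgm1 (1.34 ± 0.17). Their camera adjusted p was 4.02e-33, and adjusted p = 0.000229 with an estimated correlation. Activated microglia and macrophage markers rose in 7 of 21 cases (10 adjusted over the list alone; median 0.25), with Cd68 at 0.60 ± 0.08. Chemokines rose in 7 of 26 cases (12 adjusted over the list alone), with Ccl2 at 1.11 ± 0.15. Of the cytokines and their receptors 5 of 24 rose (12 adjusted over the list alone), with Osmr at 1.02 ± 0.16. Socs3 in that list rose by 0.82 ± 0.11 in 1 probe set and differed by -0.03 in the other.

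In the same arrays 4 of 18 NF-kB targets rose (10 adjusted over the list alone), among them Bcl3 (0.77 ± 0.11), the selectin gene Sele (0.58 ± 0.12) and Ptgs2 (0.71 ± 0.14). Complement genes rose in 3 of 15 cases (5 adjusted over the list alone), with C5ar1 at 1.17 ± 0.17, and matrix and wound genes in 5 of 22 (10 adjusted over the list alone), with Cd44 at 0.79 ± 0.13. Glucocorticoid-responsive genes rose in 2 of 14 cases, Lcn2 and Map3k6 (4 adjusted over the list alone), and antigen presentation genes in 1 of 14, H2-Q4 (6 adjusted over the list alone). TNF ligands, receptors and adaptors rose in 1 of 18 cases, Tnfrsf1a by 0.59 ± 0.10 (1 adjusted over the list alone). Oxidative stress genes rose in 2 of 16 cases, Hmox1 and Mt2 (4 adjusted over the list alone), and cell death genes in 1 of 16, Gadd45g (3 adjusted over the list alone). Neutrophil and monocyte markers had 0 of 17 past the threshold (3 adjusted over the list alone; median 0.17). These 9 lists, like the 5 in the paragraph above, passed camera upwards, with adjusted p of 0.0448 or less with an estimated correlation. The calls of Ptgs2, Map3k6, Mt2 and Gadd45g were lost with the prefix as a term (adjusted p from 0.103 to 0.171). Of the 16 fits that left out 1 array, Ptgs2 and H2-Q4 passed in 12 each, and Sele, Map3k6, Mt2 and Gadd45g in 10 each.

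Synaptic transmission genes (median -0.11, 0 of 20 past the threshold; adjusted p = 0.0448 with an estimated correlation) were shifted downwards in the arrays labelled TNF knockout. So were cortical excitatory neuron markers (median -0.11, 0 of 13; adjusted p = 0.00826 with an estimated correlation). Resident microglia markers were shifted downwards by camera but not with an estimated correlation (adjusted p = 0.264 with an estimated correlation, and adjusted p = 0.153 without stroke array 1). In that list Gpr34 fell by 0.49 ± 0.11, past the threshold in 3 of the 16 fits that left out 1 array and not with the prefix as a term (adjusted p = 0.171). The downward call was lost in the same way for oligodendrocytes (adjusted p = 0.366 with an estimated correlation), choroid plexus and ependyma (adjusted p = 0.134) and resting astrocytes (adjusted p = 0.181). It was lost as well for general neurons (adjusted p = 0.111), inhibitory neurons (adjusted p = 0.0892) and thalamus, hypothalamus and cerebellum (adjusted p = 0.0987). Each of the last 6 lists had 0 members past the limma threshold. The remaining 14 lists did not pass camera. Among them, immediate early genes had Atf3 higher (0.89 ± 0.14) and Homer1 lower, and heat shock genes had 0 of 12 past the threshold (median 0.01). The cell cycle list had Mcm6 higher, the pericyte list had Rgs5 lower, and the neighbours of Tnf had H2-Q4 and C4b higher. Mcm6, Rgs5 and C4b each passed in 5 of the 16 fits that left out 1 array and not with the prefix as a term. With the prefix as a term, camera no longer passed resting astrocytes (adjusted p = 0.393) or thalamus, hypothalamus and cerebellum (adjusted p = 0.101), and it passed the neighbours of Tnf (adjusted p = 0.0197).

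In the arrays labelled TNF knockout, 128 of 19938 genes passed the limma threshold, 107 higher and 21 lower after stroke, 25 of them at least 2-fold higher. In 1171 genes (5.87 percent) the groups did not overlap, against 2.86 percent by chance. With the prefix as a term 72 genes passed, 67 of them among the 128, with 68 higher and 4 lower. Within KL76 17 passed and within KL82 6, where 3 arrays were set against 1, so the spread of that single array was taken from the other groups. The decreases rested on single arrays more than the increases did. Higher and lower genes were 68 and 4 without naive array 1, 68 and 2 without naive array 2, 89 and 7 without naive array 3, and 80 and 28 without naive array 4. They were 80 and 12, 93 and 8, 65 and 6, and 66 and 3 without stroke array 1, 2, 3 or 4.

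The stroke changes in the 2 genotypes, which share no arrays, had Pearson's r = 0.396 and Spearman's rho = 0.212 across all genes tested, and r = 0.241 with the prefix as a term in the arrays labelled TNF knockout. Over the 397 genes past the threshold in either, selected for their change, r was 0.773, and genes are not independent replicates. Past the threshold in both were 65 genes, 58 higher and 7 lower, with 0 in opposite directions, against 1.43 higher and 0.0706 lower for independent lists. Of the 334 genes called in C57BL/6 mice 288 had the same sign in the arrays labelled TNF knockout, and of the 128 called there 114 had the same sign in C57BL/6 mice.

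**Figure D2:**
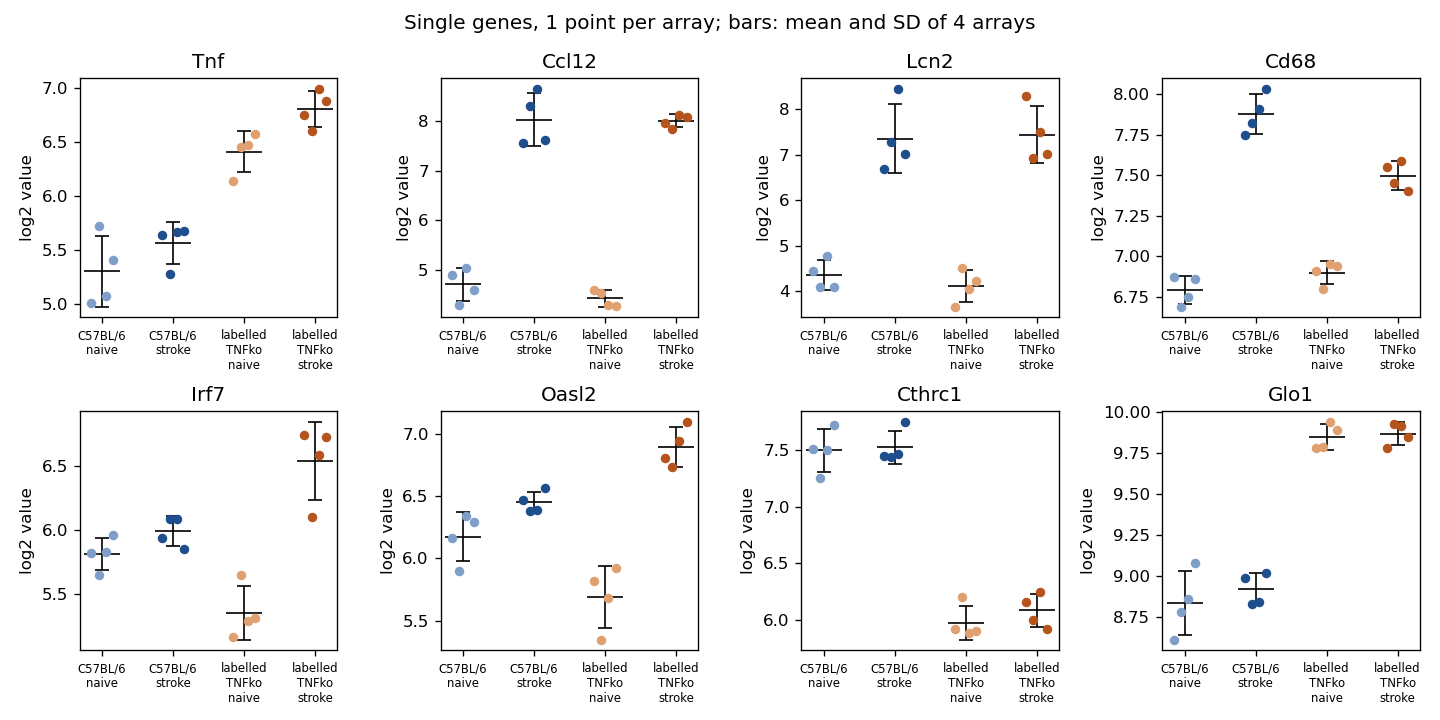
Log2 value of 8 genes in each array, by group, with the group mean and SD (n = 4 per group). Every array labelled TNF knockout lies above every C57BL/6 array for Tnf (6.14 or higher against 5.72 or lower) and Glo1, and below for Cthrc1.

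The comparison of naive arrays labelled TNF knockout with naive C57BL/6 arrays asks how the brains differ before stroke. Besides Tnf, Catspere2, a subunit of the sperm calcium channel, was higher in the arrays labelled TNF knockout (7.91 ± 0.17 against 6.80 ± 0.21; 1.10 ± 0.10, adjusted p = 6.9e-06). Glo1, which detoxifies methylglyoxal, was higher as well (9.85 ± 0.08 against 8.83 ± 0.20; 1.02 ± 0.09, adjusted p = 5.6e-06). The lipoprotein lipase gene Lpl (1.03 ± 0.11), the microRNA gene Mir377 (0.95 ± 0.11), Rgcc (0.91 ± 0.14) and Abhd1 (0.88 ± 0.12) were also higher. Cthrc1, which encodes a secreted collagen-related protein, was lower (5.97 ± 0.15 against 7.50 ± 0.19; -1.52 ± 0.11, adjusted p = 2.1e-07). Trim12a (-1.27 ± 0.22, past in 13 of the 16 fits that left out 1 array), Nnt, the mitochondrial transhydrogenase gene (-0.64 ± 0.08), Baalc (-0.60 ± 0.09) and Bpnt1 (-0.58 ± 0.09) were lower too. Marchf11 was higher by 0.77 ± 0.12 in 1 probe set, and its other probe set differed by 0.00.

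Few members of the fixed lists separated the naive groups. The immediate early gene Junb was lower in the arrays labelled TNF knockout (-0.52 ± 0.11, adjusted p = 0.034, past in 10 of the 16 fits that left out 1 array), 1 of 25 in its list, and in the other 36 lists 0 members passed the limma threshold. Camera placed 3 lists lower in the arrays labelled TNF knockout, and 0 of the 3 kept the call with an estimated correlation. Oligodendrocyte markers had a median of -0.26 (4 of 11 adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.704 with an estimated correlation). Antigen presentation genes had a median of -0.19 (3 of 14 adjusted over the list alone; adjusted p = 0.0203, adjusted p = 0.446 with an estimated correlation). The neighbours of Tnf had a median of -0.10 (1 of 44 adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.446 with an estimated correlation). Without naive C57BL/6 array 4 each of these had adjusted p = 0.0511, and without naive array 1 of those labelled TNF knockout the first 2 had adjusted p = 0.0973. Antigen presentation also missed without naive C57BL/6 array 1 (adjusted p = 0.0545). Interferon-stimulated genes had a median of -0.08 and did not pass (adjusted p = 0.109), with Oasl2 at -0.48 ± 0.12 (adjusted p = 0.081).

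In naive mice 77 genes passed the limma threshold, 44 higher and 33 lower in the arrays labelled TNF knockout, 5 and 2 of them by at least 2-fold. The balance of directions depended on scaling and on single arrays, with 31 higher and 38 lower after quantile normalization and 37 higher and 47 lower after median centring. In 1724 genes (8.65 percent) the groups did not overlap, against 2.86 percent by chance. Every C57BL/6 array has the prefix KL42 and every array labelled TNF knockout has KL76 or KL82, so genotype and prefix cannot be told apart in this comparison or in the same comparison after stroke. The count was 41 (18 higher and 23 lower), 23 and 29 without naive C57BL/6 array 1, 3 or 4. It was 138, 27, 28 (13 higher and 15 lower) and 33 (16 and 17) without naive array 1, 2, 3 or 4 of those labelled TNF knockout.

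After stroke, the comparison of the same genotypes asks whether the injured brains differ. Catspere2 (1.47 ± 0.10, adjusted p = 1.4e-07), Glo1 (0.95 ± 0.09), Lpl (0.83 ± 0.11), Abhd1 (0.82 ± 0.12) and Mir377 (0.75 ± 0.11) were again higher in the arrays labelled TNF knockout. Ifi202b, an interferon-inducible DNA sensor gene, was higher by 1.16 ± 0.12 (adjusted p = 2.1e-05) and Entpd4, a nucleotidase of the Golgi, by 0.84 ± 0.10. In naive C57BL/6 arrays Ifi202b read 3.08 or lower, far below the array medians of 6.01 to 6.05. Whether such readings lay above background is not known. Slfn4 was higher by 1.25 ± 0.27 (adjusted p = 0.041, past in 6 of the 16 fits that left out 1 array). Cthrc1 (-1.45 ± 0.11), Cpq, a plasma dipeptidase gene (-1.14 ± 0.13), and Myl4, a myosin light chain gene (-0.93 ± 0.11), were lower. So were Snapc1 (-0.89 ± 0.14), Bpnt1 (-0.69 ± 0.09), Baalc (-0.68 ± 0.09) and the antioxidant lactonase gene Pon2 (-0.67 ± 0.10).

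Oligodendrocyte markers were lower after stroke in the arrays labelled TNF knockout, with a median of -0.37 and 9 of 11 adjusted over the list alone. Over all genes 2 of 11 passed, the myelin genes Cnp (-0.46 ± 0.08) and Mal (-0.53 ± 0.10). Camera gave adjusted p = 5.8e-11, and adjusted p = 0.103 with an estimated correlation. Oligodendrocyte precursor markers were lower in 2 of 9 cases, Olig1 (-0.45 ± 0.09) and Gpr17 (-0.52 ± 0.11), with 3 adjusted over the list alone and adjusted p = 0.111 with an estimated correlation. Interferon-stimulated genes were higher in 2 of 23 cases, Stat2 (0.41 ± 0.08) and Ifit3 (0.69 ± 0.15), with 10 adjusted over the list alone and a median of 0.29 (camera adjusted p = 1.5e-09, adjusted p = 0.103 with an estimated correlation). Activated microglia and macrophage markers were lower (median -0.13; adjusted p = 0.111 with an estimated correlation), with Cd68, 1 of 21, at -0.38 ± 0.08 (4 adjusted over the list alone). Complement genes were lower (median -0.18; adjusted p = 0.111 with an estimated correlation), with C1qc, 1 of 15, at -0.65 ± 0.11 (3 adjusted over the list alone), and missed without stroke array 4 labelled TNF knockout (adjusted p = 0.0571). Endothelial markers were lower (median -0.20; adjusted p = 0.111 with an estimated correlation), with the tight junction gene Cldn5, 1 of 13, at -0.53 ± 0.11 (1 adjusted over the list alone). Resident microglia markers (median -0.21, 0 of 12; 3 adjusted over the list alone; adjusted p = 0.348 with an estimated correlation) and heat shock genes (median -0.21, 0 of 12; 1 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation) were lower as lists. So 8 lists passed camera and 0 of them kept the call with an estimated correlation. Of the 44 neighbours of Tnf, 1 was lower, Gtf2h4 (-0.49 ± 0.09), and reactive astrocyte markers had a median of 0.08 with 0 of 20 past the threshold (camera adjusted p = 0.343). Of the 16 fits that left out 1 array, Mal passed in 13, Gtf2h4 in 12, Olig1 and Gpr17 in 11 each, Stat2 and Cd68 in 10 each, Ifit3 in 6 and Cldn5 in 5.

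After stroke 87 genes passed the limma threshold, 33 higher and 54 lower in the arrays labelled TNF knockout, and 4 in each direction by at least 2-fold. In 1157 genes (5.80 percent) the groups did not overlap, against 2.86 percent by chance. The count was 47 (20 higher and 27 lower) without C57BL/6 stroke array 4, and 57 (21 and 36) and 54 (21 and 33) without stroke array 1 or 4 of those labelled TNF knockout. The excess of lower genes rested on single arrays, with 34 higher and 33 lower without stroke array 2 labelled TNF knockout, and 39 and 81 without C57BL/6 stroke array 1. Past the threshold both in naive mice and after stroke were 25 genes, 12 higher and 13 lower, against 0.0728 and 0.0894 for independent lists, and the 2 comparisons share no arrays (r = 0.335 across genes, which are not independent replicates).

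**Figure D3:**
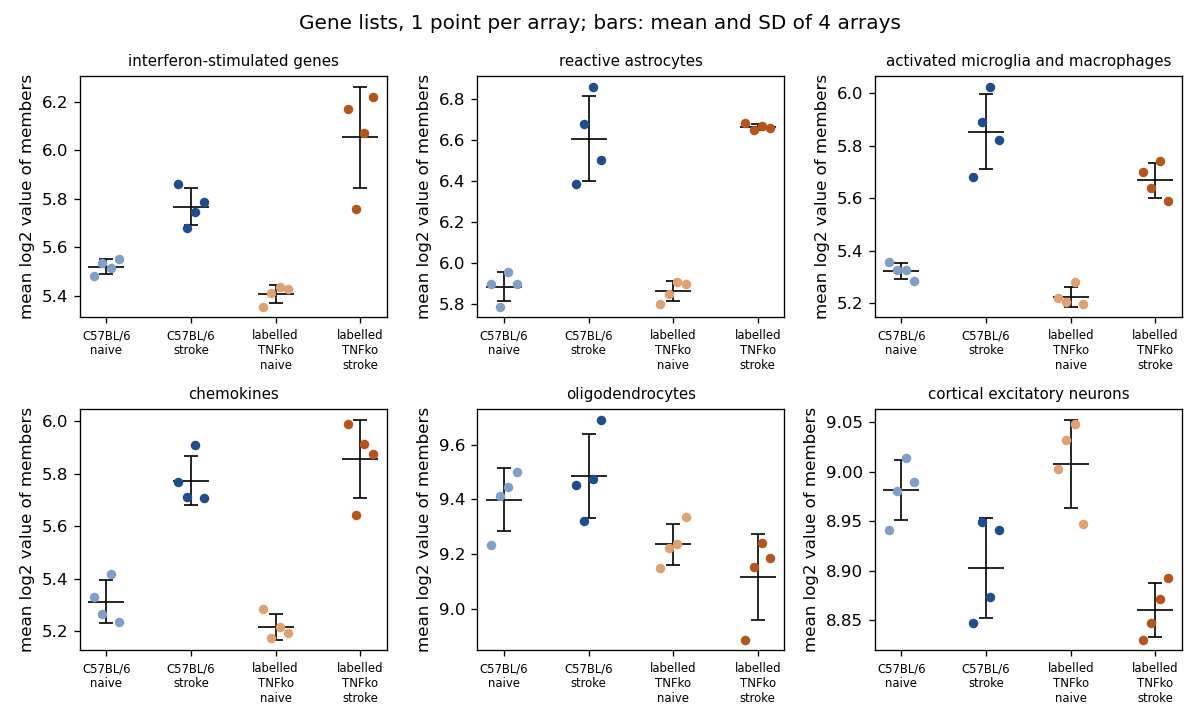
Mean log2 value of the measured members of 6 fixed lists in each array, by group, with the group mean and SD (n = 4 per group). For interferon-stimulated genes 3 of the 4 stroke arrays labelled TNF knockout lie above the highest C57BL/6 stroke array.

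Whether the stroke change itself differed between genotypes was tested as the difference of the changes, arrays labelled TNF knockout minus C57BL/6. No gene passed: limma gave 0 of 19938, with a smallest adjusted p of 0.0806 and 1480 genes at an unadjusted p under 0.05. The median SE was 0.141, against 0.0994 for the stroke change in either genotype, so differences may have been missed. The 5 genes with the smallest p were Ifi202b (1.04 ± 0.16), Adat2 (-1.01 ± 0.18), Irf7 (1.01 ± 0.18), Oasl2 (0.92 ± 0.17) and Klk1b1 (0.78 ± 0.15), a kallikrein gene, with adjusted p from 0.0806 to 0.180. The change of Ifi202b starts from naive C57BL/6 readings of 3.08 or lower, which may lie within background. In C57BL/6 mice Irf7 differed after stroke by 0.18 ± 0.13 and Oasl2 by 0.28 ± 0.12, neither past the threshold. Other fits passed 4 genes with trended and robust variances (Adat2, Ifi202b, Irf7 and Oasl2), 1 with array weights (Ifi202b) and 1 with the replicate number as a block (Oasl2). Tnf had a difference of 0.13 ± 0.20 (adjusted p = 0.90), Ccl3 of 0.77 ± 0.44 (adjusted p = 0.71) and Cd68 of -0.49 ± 0.11 (adjusted p = 0.41).

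For 7 lists camera found a different stroke change, and 0 of them kept the call with an estimated correlation. The change of interferon-stimulated genes was larger in the arrays labelled TNF knockout, by a median of 0.29 and in 22 of 23 members (camera adjusted p = 2.0e-11, adjusted p = 0.162 with an estimated correlation). In that list 5 genes passed adjusted over the list alone, among them Irf7 and Oasl2. The difference was positive too for chemokines (median 0.12) and antigen presentation genes (median 0.12). It was negative for heat shock genes (median -0.20, with Dnajb1 at -0.47 ± 0.11), resident microglia markers (median -0.27, with Gpr34 at -0.61 ± 0.16), oligodendrocyte markers (median -0.20) and endothelial markers (median -0.21). For these 6 lists the adjusted p lay between 0.00197 and 0.0160, and between 0.321 and 0.541 with an estimated correlation. Chemokines, antigen presentation, oligodendrocytes and endothelial cells each passed in 12 of the 16 fits that left out 1 array. With the prefix as a term the endothelial list missed the threshold (adjusted p = 0.0956), the other 6 passed, and NF-kB targets joined them (adjusted p = 0.0146).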

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

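The tests of wrong or exchanged genotype labels, of placement on chromosomes by chance, of DNA carried along with the targeted allele, and those of the interferon-stimulated genes were chosen only after the result was seen. The splits of the arrays and the comparison with the sample name prefixes were set out before.

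Tnf was higher in the arrays labelled TNF knockout, against the label. A single wrong label is argued against by the ranges, since the lowest of the 8 arrays so labelled lay 0.42 (log2) above the highest of the 8 C57BL/6 arrays. An exchange of the genotype labels of all arrays could not be decided, because Tnf did not pass for stroke in either genotype and the stroke changes differed by 0.13 ± 0.20. The C57BL/6 readings of Tnf also lay below the array medians, where a response may be missed. Which part of Tnf the probe set covers relative to the deletion is not given in the sources used here, so a transcript from the altered allele may still be read by it. Every statement on direction between genotypes rests on the labels as given.

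The genes that differed between genotypes lay next to each other on chromosomes. Of 139 genes past the threshold in naive mice or after stroke, 50 had another such gene within 10 tested genes along GRCm38.p6, against a median of 18 and a highest value of 41 in 10000 random sets (permutation p = 1e-04, the smallest these sets can give), but the stroke genes, where strain or flanking DNA is not compared, also had more neighbours than random sets (30 of 128 against 15, p = 0.0055, in the arrays labelled TNF knockout, and 118 of 334 against 95, p = 0.0189, in C57BL/6 mice). Of the genes with a neighbour 72 percent lie off chromosome 17, a share that was not compared with random sets. For the stroke genes in the arrays labelled TNF knockout this share was 100 percent. As many genes with the smallest p between KL76 and KL82 gave 18 with a neighbour (permutation p = 0.528), 88.9 percent of them off chromosome 17. The 72 percent therefore cannot decide on DNA around Tnf as the whole cause. An array run that coincides with genotype cannot be told apart either. Only 3 genes passed the threshold between KL76 and KL82, so the comparison of these prefixes could not show what a run does. For the part on chromosome 17, 21 genes passed there against 6.50 in random sets (permutation p = 1e-04). Within 100 tested genes of Tnf 1 passed (Gtf2h4) against 1.39 (permutation p = 0.758), which gives no excess among the genes tested there. Of 50 listed neighbours of Tnf 6 were not tested, among them H2-D1 and H2-Q7. Of the 7155 probe sets left out for their symbols, 74 passed between genotypes in naive mice, and their places were not examined. An excess next to Tnf may therefore have been missed. DNA carried along from farther along the chromosome cannot be told apart from other differences there. A difference in strain background beyond the targeted gene may give such groups of neighbours, as may shared regulation of neighbouring genes, and neither was tested.

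Interferon-stimulated genes were higher after stroke in the arrays labelled TNF knockout, by 0.286 in the mean of the list, a shift that passed camera but not with an estimated correlation (adjusted p = 0.103, and adjusted p = 0.162 for the difference of the stroke changes). A single array is argued against by the lowest difference with 1 of these 4 arrays left out, 0.231, beside an SD between arrays of 0.113. Entering the prefixes KL76 and KL82 as a term did not remove the difference. The stroke change still exceeded that in C57BL/6 mice by 0.430 ± 0.125 (SE pooled over the 16 arrays). This joins an excess of 0.521 in KL76 with 1 stroke array and of 0.340 in KL82 with 1 naive array. A constant offset between genotypes, such as an array run, would give equal differences in naive and stroke arrays. The naive arrays differed the other way, by -0.112, with all 4 arrays labelled TNF knockout (5.44 or lower) below all 4 C57BL/6 arrays (5.48 or higher). The stroke and naive differences lay 0.398 ± 0.113 apart (exact permutation p = 0.00449, adjusted p = 0.166 over the 37 lists). Both checks measure again the difference for which this list was picked. Its adjusted p-values leave that difference open, so the checks cannot rule out the prefixes or an offset. A larger response of glia overall remained open, with activated microglia at -0.187 and reactive astrocytes at 0.0588 (exact permutation p = 0.0571 and p = 0.200 for the interferon list's difference against each of theirs), and a biological difference tied to Tnf may only be considered once the label of Tnf is settled.

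Other splits of the same arrays were counted for each comparison. With 35 splits, 1 of 35 is the smallest possible share, and shares were not adjusted over the comparisons. Other splits mix arrays of the compared groups, which can widen the spread and lower their gene counts. Chance is therefore not excluded by these counts. For stroke in C57BL/6 mice chance is argued against for the 334 genes (highest other split 5, and 1 of 35 splits as large, the real one) but not for the 15 lists (highest other 20, and 5 of 35). For stroke in the arrays labelled TNF knockout it is argued against for the 128 genes (highest other 12, a split that follows the prefixes, and 1 of 35). For the 23 lists the margin was small (highest other 21, and 1 of 35), which leaves chance open. Between genotypes in naive mice chance is argued against for the 77 genes (highest other 1, and 1 of 35) but not for the 3 lists (highest other 5, and 6 of 35). After stroke it is argued against for the 87 genes (highest other 5, and 1 of 35) but not for the 8 lists (highest other 16, and 13 of 35). For the difference of the stroke changes it cannot be excluded for the 7 lists (highest other 13, and 21 of 100). For the genes limma gave 0 (1480 at an unadjusted p under 0.05, and up to 4 in other fits), so 100 of 100 splits gave as many by necessity (highest other 1) and say nothing about chance.

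Of 308 sets of 4 arrays of a named gene, 23 had 1 array far from the other 3 by Dixon's ratio, where about 1 in 20 is expected by chance. In C57BL/6 naive arrays these were Osmr 5.09 and Ifi202b 3.08 (array 3), Dnajb1 7.63 (array 1) and Catspere2 7.12 (array 2). In C57BL/6 stroke arrays they were Shank1 8.29 (array 1), Tnf 5.28 (array 2), Stat2 7.38 (array 3) and, in array 4, Rpe65 3.67, Cthrc1 7.75, C1qc 8.51 and Gpr34 5.02. In naive arrays labelled TNF knockout they were Cthrc1 6.20 (array 2), Bcl3 5.67 (array 3) and, in array 4, Ccl3 5.27, Homer1 9.24 and Ptgs2 7.40. In stroke arrays with that label they were Serpina3n 10.19, Sele 6.14 and Nfkb2 6.29 (array 1), Lilr4b 5.18, H2-Q4 5.78 and C3ar1 6.45 (array 2) and Mx1 3.89 (array 4).

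The stroke change of 7 lists differed between genotypes by camera, 0 of them with an estimated correlation, with medians of 0.1175 for chemokines, 0.2875 for interferon-stimulated genes, 0.1225 for antigen presentation, -0.1975 for heat shock, -0.265 for resident microglia, -0.205 for oligodendrocytes and -0.215 for endothelial cells. Of 7155 probe sets with no symbol or several, which were left out of the gene-level tests, 17 and 47 passed for stroke in C57BL/6 mice and in the arrays labelled TNF knockout, and 74 and 41 passed between genotypes in naive mice and after stroke.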

How the results depend on the processing

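Camera with the prefix as a term, list medians within a prefix, the linear model of the interferon list's mean with the prefix as a term and the exact permutation tests of lists were added only after the result was seen, and the other settings were set out before. The counts of genes past the threshold moved by over 1.5 times in some settings, and the cause was not tested. For stroke in C57BL/6 mice, 334 became 536 without the dimmest 33.3 percent of genes, 222 with all probe sets tested, 516 with trended and robust variances, 98 with only the groups compared, 559 with the replicate number as a block, 76 at adjusted p under 0.01 and 93 with a 1.5-fold change required. It ranged from 107 (without C57BL/6 stroke array 3) to 639 (without C57BL/6 stroke array 1, whose array weight was 0.509). For stroke in the arrays labelled TNF knockout, 128 became 212 with array weights, 72 with the prefix as a block, 17 within KL76, 6 within KL82, 54 at adjusted p under 0.01 and 76 with 1.5-fold, and 69 to 145 with 1 array left out (stroke array 4 with that label and C57BL/6 stroke array 1). Between genotypes in naive mice, 77 became 185 without the dimmest genes, 167 with all probe sets, 51 with only the groups compared, 141 with the replicate block, 20 at adjusted p under 0.01 and 24 with 1.5-fold. It ranged from 23 (without C57BL/6 naive array 3) to 138 (without naive array 1 labelled TNF knockout). After stroke, 87 became 164 without the dimmest genes, 135 with all probe sets, 162 with trended and robust variances, 46 with only the groups compared, 36 at adjusted p under 0.01 and 36 with 1.5-fold, and 47 to 120 with 1 array left out (C57BL/6 stroke arrays 4 and 1). For the difference of the stroke changes, limma gave 0 (1480 at an unadjusted p under 0.05), and other fits gave 4 with trended and robust variances, 1 with array weights, 1 with the replicate block and 0 to 3 with 1 array left out (3 without C57BL/6 naive array 2). The 56 list calls became 24 with an estimated correlation and 50 to 67 with 1 array left out. The correlation of the stroke changes between genotypes, 0.396, was 0.523 without the dimmest genes, 0.773 over the genes past the threshold in either genotype, 0.241 with the prefix as a block, and 0.282 to 0.441 with 1 array left out (naive array 1 and stroke array 1 labelled TNF knockout). The labels do not say that a replicate number is shared between groups, and not every pair of arrays with the same number had residuals correlated above 0.1, so the numbers were taken as names. Over 0.1 were 1 of 4 pairs for stroke in C57BL/6 mice (mean 0.04) and 3 of 4 for stroke in the arrays labelled TNF knockout (mean 0.18). Between genotypes they were 1 of 4 in naive mice (mean 0.09) and 3 of 4 after stroke (mean 0.13). Pairs with different numbers had lower means, -0.01, -0.06, -0.03 and -0.04 in the same order. Of 8 arrays 2, 4, 6 and 6 went best with their own number. On the first principal component of the residuals, array 1 was negative in all 4 groups. Its values were -2.203 and -18.81 in naive and stroke C57BL/6 mice, and -12.26 and -13.36 with the TNF knockout label. Array 4 was positive in all 4 (5.233, 10.95, 9.741 and 7.175), and arrays 2 and 3 had both signs. These hints from the data leave a shared factor open. With the number as a block Oasl2 passed for the difference of the stroke changes (adjusted p = 0.0168). No named gene past the threshold changed direction in the settings run for it. Medians of the lists past camera kept their sign with quantile normalization, median centring and 1 array left out.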

Other observations

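In the genes past the threshold for stroke in C57BL/6 mice, the median ratio of the change in the arrays labelled TNF knockout to that in C57BL/6 mice was 0.42. For the genes past it in the arrays labelled TNF knockout, the median ratio of the change in C57BL/6 mice to theirs was 0.74. Selection of genes by the first change alone lowers such a ratio, and the difference of the changes passed limma for 0 genes (1480 at an unadjusted p under 0.05, and up to 4 in other fits). Cd68 rose in both, by 1.08 and 0.60, and the difference of -0.49 did not pass (adjusted p = 0.41).

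Ccl12 rose by 3.33 and 3.58 in the 2 genotypes, a difference of 0.26 ± 0.27 (adjusted p = 0.84). Lcn2 differed by 0.32 (adjusted p = 0.88) and Cxcl10 by 0.80 (adjusted p = 0.68). Slfn4 rose 2.29 in the arrays labelled TNF knockout and differed by 1.45 (adjusted p = 0.43).

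Some of the groups of neighbouring genes that differed between genotypes hold genes with large differences. On chromosome 15 Baalc and Cthrc1 lie in 1 group and Cpq and Atpsckmt in another, and on chromosome 17 Zfp983 lies in a group of zinc finger genes. On chromosome 1 Ifi202b lies in a group with Ackr1 and Olfr231. These examples were chosen after their values were seen. Of the 50 genes with such a neighbour, 11 lie on chromosome 15, 14 on chromosome 17 and 25 elsewhere.

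The sign of the list median differed from that of the mean or of camera in several lists that did not pass, such as chemokines after stroke between genotypes (median -0.02, mean 0.08).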
